A study of Caenorhabditis elegans with 2 samples.

How the data were processed

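Whole young adult hermaphrodites of Caenorhabditis elegans strain OP460 were used for ChIP-seq of NHR-80 fused to GFP and FLAG, with chromatin sheared by sonication, per the labels. The labels differ on the antibody: the description names GFP as its target, which was followed here, and another field names nhr-80. The 2 samples are biological replicates 1 and 2 of 1 group, per the labels, and no other group was analysed here. The deposited files are peak lists in the narrowPeak layout. For each of the builds ce10 and ce11 there are 4: one list of peaks and background for each replicate, one for both replicates pooled, and the optimal list thresholded by IDR. The IDR method sets a limit from how well the ranks of peaks reproduce between replicates. Per the file headers and notes deposited with the samples, the lists were called against a control, and the thresholded list was derived from the replicate and pooled lists. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here.

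The signal value of each peak is the authors' own, on the peak caller's scale, and was used only to rank and describe peaks within a list. The deposited −log10 q values reach a ceiling in each list (4.37 in the thresholded ce11 list, held by all 7038 of its peaks) and were not used to rank. Read counts are not part of peak lists, so the depth per library is unknown and no value here carries an interval from depth. A change of the caller or the threshold would change how many peaks are listed, and the control decides how well regions of open or abundant chromatin are corrected.

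Coordinates are those of the authors' ce11 lists, written 1-based, and none were converted between builds. They were compared with the WBcel235 genome, which is the assembly of ce11, and with the gene annotation of Ensembl release 115. The 18 thresholded peaks on mitochondrial DNA were left out of the location, gene, motif and chromosome results. The promoter of a protein-coding gene was the window from 1000 bp upstream to 200 bp downstream of its annotated 5' end. Each summit was put into the first class that held it, in the order promoter, 5' UTR, 3' UTR, coding exon, intron, noncoding gene and intergenic. A summit counted for every gene whose window held it, which concerned 684 of the 7020 nuclear peaks.

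Peaks were called shared when they overlapped by at least 1 bp. For the replicates, the 7038 strongest peaks of each were used, as many as the thresholded list held. Chance values came from 100 rounds in which all peaks of a chromosome were moved by 1 random distance, wrapping round its end. Location classes were compared with the pooled peaks that overlapped no thresholded peak, by two-sided Fisher's exact tests. Gene lists were compared with all other protein-coding genes by the same test. The 32 lists covered lipid metabolism, regulators, cell machinery, gene families and markers of the intestine and of other tissues. Genes in a list can share promoters or lie in clusters, so they are not independent, and the p-values treat them as if they were. Sequences were counted on either strand within 50 bp of the summit and in flanks of the same total width from 200 to 250 bp, by a two-sided exact McNemar test on the peaks that differed. The flanks on each side were separate stretches, so a sequence had slightly fewer possible positions there than at the summit. This raises the ratios of summits to flanks slightly. Adjusted values are Benjamini-Hochberg values within each family of tests, with a threshold of 0.05. Shares carry 95% Wilson intervals, or exact binomial ones for chromosomes, which cover counting error only. In the main test of the gene lists, a share of 0 carries the limit that 3 counts would give.

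Genes were named by a rule set before the data were examined, as were the lists, sequences, tests and most alternatives. The rule took the 25 protein-coding genes with the strongest promoter peak that overlapped a strong peak in both replicates, naming the nearest start where windows overlapped. It also took the 7 desaturase genes, nhr-80, nhr-49, nhr-13, mdt-15, sbp-1, lipl-4, acs-2 and unc-119 whatever their peaks, and up to 4 members of each list with the strongest promoter peak.

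The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap function was checked against bedtools 2.31.1, and both found 6462 of the 7038 strongest peaks of replicate 1 overlapping those of replicate 2. The gene list test was tested on simulated data for 19973 genes. In 20 rounds with 6 lists raised to 50%, it called 91 of 120 raised lists and 3 of 460 unraised ones. Genes were drawn independently there, so these rates do not cover shared promoters or clusters. The smallest lists, such as desaturases and vitellogenins, and the largest were never raised. TGATAA planted in 5% of 7020 real flank sequences raised its share by 4.44 percentage points, and 0 of 200 random 6-mers were called between unplanted sequences. Both sides of that check were flank sequence, so it does not cover the difference in base composition between summits and flanks.

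Alternatives were the thresholded peaks above the median signal, each replicate's own strongest peaks, other rules for overlap, other promoter windows, the nearest start alone, another gene background, other motif windows, merged summits and the ce10 list. A longer list with as many ce11 peaks as the ce10 list, and gene lists without peaks near small RNA genes, were added after seeing the data.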

Results

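Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where NHR-80 sits on the genome of Caenorhabditis elegans. NHR-80 is a nuclear hormone receptor of the HNF4-like class, known from earlier work for its part in the control of fatty acid desaturase genes. The animals were hermaphrodite young adults of the transgenic strain OP460, collected whole 64 hours after synchronisation at the L1 stage. The strain carries an integrated nhr-80 transgene with a GFP-FLAG tag at the C terminus, in an unc-119 mutant background, and by the sample description the tagged protein was recovered with an antibody against GFP. There was 1 group with 2 biological replicates, so the comparisons were between replicates, between peaks that passed the authors' reproducibility threshold and those that did not, and between list members and other genes. The lists held 30000 peaks for replicate 1, 29712 for replicate 2 and 30000 for both replicates pooled on build ce11. Of the pooled peaks, 7038 were in the list thresholded by irreproducible discovery rate (IDR), and 7020 of these were on the nuclear chromosomes. The depth of each library is unknown, because the peak lists carry no read counts.

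The first question was how far the 2 replicates placed peaks at the same sites. The thresholded peaks are the strongest of both replicates pooled, down to a limit set by IDR from the replicates. Their overlap with the replicates and the correlation across them therefore do not measure agreement independently. Of these 7038 peaks, 6324 (89.9%) overlapped a peak among the 7038 strongest of both replicates. Replicate 1 covered 94.8% of the thresholded peaks and replicate 2 covered 94.4%. Moving the peaks of each chromosome together by a random distance gave a mean of 4.49% and at most 5.07% in 100 shifts. The replicates' own 7038 strongest peaks, taken from each list alone, overlapped each other at 91.8% from either side. Each thresholded peak was given the signal value of the strongest peak it overlapped in each replicate's full list. Across the 7016 thresholded peaks found in both, these values had a Spearman rho of 0.93 (95% interval 0.93 to 0.94), which describes peaks and not independent samples. In the thresholded list, 407 peaks had the same interval as a stronger one, so some pairs of values occur more than once. The strongest promoter peak among protein-coding genes, at serp-1.1, ranked 2 in each replicate's list, and the peak at rpl-3 ranked 6 in replicate 1 and 14 in replicate 2.

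**Figure D1:**
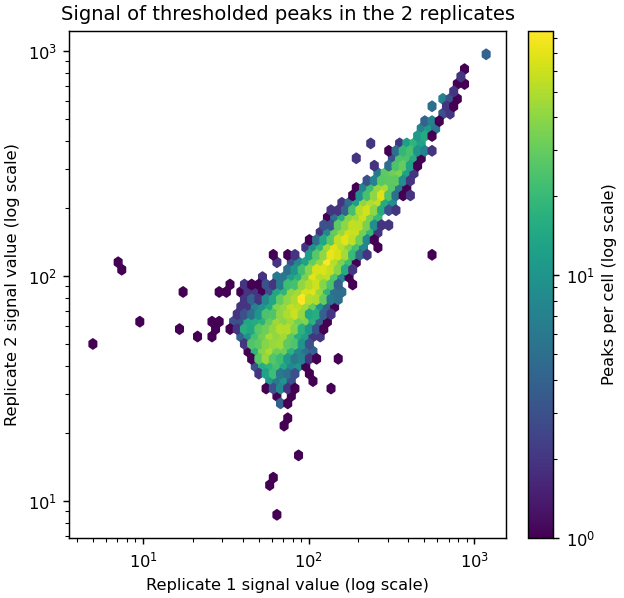
Signal value of the strongest peak that each thresholded peak overlapped in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), in the peak caller's own units. Colour gives the number of peaks per hexagon (log scale) for the 7016 peaks found in both lists. Thresholded peaks that overlap the same replicate peaks repeat their values. The peaks lie along 1 line, with a Spearman rho of 0.93.

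The second question was where in genes the peaks lay. Promoters held 3349 of the 7020 nuclear thresholded summits (47.7%), against 26.0% of the 19750 pooled peaks that did not overlap a thresholded peak. Coding exons held 3.45% against 20.6%, and 3' UTRs 1.14% against 5.81%. Introns held 22% against 29.9%, while intergenic sequence held 22% against 14.9%. Annotated noncoding genes held 2.52% against 1.76%, and 5' UTRs held 1.23% against 1.08%. Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg over the 7 classes, gave 1.58e-237 for promoters and 1.51e-311 for coding exons. The other adjusted values were 1.42e-73 for 3' UTRs, 8.96e-38 for introns, 5.88e-40 for intergenic sequence and 0.000157 for noncoding genes. The difference in 5' UTRs did not pass (adjusted p = 0.321, Fisher's exact test). Promoters held 47.4% ± 0.297 (SD, n = 2) of each replicate's own strongest peaks and a mean of 21.3% of shifted summits. Against shifted summits, coding exons (mean 19.5%), 3' UTRs (2.61%) and introns (30.4%) were also lower, while intergenic sequence was at the shifted mean of 22.1%. The share of 5' UTRs lay above every shift (mean 0.817%, highest 1.08%). The noncoding gene class turned direction, since its 2.52% lay below every shift (mean 3.40%, lowest 2.72%). That class takes all genes not annotated as protein-coding, and only summits outside the earlier classes. It does not show fewer peaks near every kind of noncoding gene: 239 summits of any class lay within 200 bp of tRNA genes, against at most 34 in the shifts. The median distance from a summit to the nearest protein-coding gene start was 842 bp, against 1424 bp for the other pooled peaks and a mean of 1635 bp after shifting. It was 848 ± 19.8 bp (SD, n = 2) in the replicates' own lists. In all, 41.1% of summits lay within 500 bp of a start and 28.7% lay more than 2000 bp away.

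**Figure D2:**
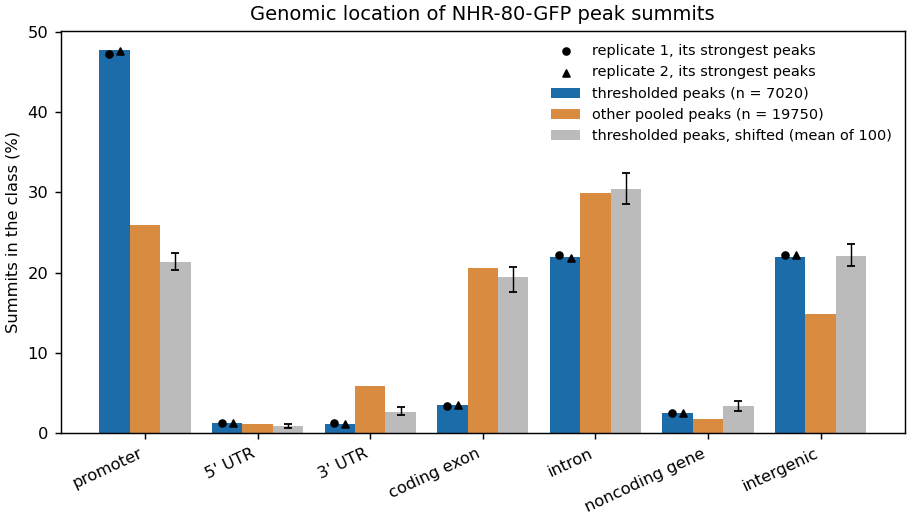
Share of peak summits (y axis, percent) in each location class (x axis) for the 7020 thresholded peaks, the 19750 other pooled peaks and the thresholded peaks after 100 random shifts (mean, with bars from lowest to highest), with points for each replicate's own strongest peaks. Promoters hold 47.7% of thresholded summits and 26.0% of the others, and coding exons hold 3.45% and 20.6%.

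Chromosome X carried more NHR-80 peaks for its length than any autosome. It held 1632 of the 7020 nuclear peaks, or 23.2% (95% exact binomial interval 22.3 to 24.3), on 17.7% of the nuclear genome, which is 92.1 peaks per Mb. The autosomes ranged from 59.5 per Mb on chromosome IV to 72.3 per Mb on chromosome III. Outside promoters the density was 54.7 per Mb on X and 28.9 to 37.7 per Mb on the autosomes, while promoter peaks reached 37.4 per Mb on X and 28.6 to 35.3 per Mb on the autosomes. Replicate 1 placed 23.3% of its strongest peaks on X and replicate 2 placed 23.7%. The pooled peaks that did not overlap a thresholded peak had 15.3% on X. By an exact binomial test over the 6 chromosomes, X was above its share of the genome (adjusted p = 2.07e-31). Chromosomes I (13.3%), IV (14.8%) and V (19%) were below theirs, with adjusted p of 6.38e-05, 1.20e-08 and 0.000158 in the same exact test.

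Among single genes, the strongest promoter peaks were at genes of varied function, and no test of a shared function was made for them. The 25 strongest that overlapped strong peaks in both replicates had pooled signal values from 955 to 1709, and 11 of these genes are on X. The first was serp-1.1 (X: 15841572 to 15842379), whose peak at X: 15840972 to 15841600 had its summit at -281 bp from the start and a signal value of 1709. The less studied F16G10.6 (1580) and tasp-1, for a threonine aspartase (1523), came next. Protein synthesis was represented by rpl-3, a large ribosomal subunit protein (III: 3867854 to 3869587, signal 1388), and iff-2, a homologue of the translation factor eIF5A (signal 1071). For secretion, trap-2, a subunit of the translocon-associated complex, had a value of 1351, and hsp-3, an Hsp70 chaperone of the endoplasmic reticulum, had 1311. The unfolded protein response factor xbp-1 (III: 4193809 to 4195358) had 1014, with its summit at -56 bp from the start.

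Signalling and regulatory genes in the same group of 25 were sem-5, a Grb2-like adaptor (1370), puf-9, an RNA-binding protein of the Pumilio family (1272), and nipi-3, a Tribbles-like pseudokinase (961). They also included the nuclear hormone receptor gene nhr-35 (1192) and the zinc finger factor gene sptf-2 (958). The intestinal oligopeptide transporter gene pept-1 (X: 6456872 to 6461767) had 988, with values of 506 in replicate 1 and 478 in replicate 2 on those lists' own scales. Enzyme genes were sucl-1, for a subunit of succinyl-CoA ligase (996), rib-2, for a heparan sulfate glycosyltransferase (990) and pcp-1, for a prolylcarboxypeptidase-like protease (1055). The remaining genes were sym-4 (1316), mekk-3 (1092), wip-1 (999.9), maph-1.1 (977) and the less studied K04B12.2 (1030), C05G5.2 (1013), K12H4.5 (1006) and Y95B8A.6 (955).

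A further question was whether peaks lay at the genes through which the role of NHR-80 in fat metabolism is known. Of the 7 fatty acid desaturase genes, fat-3, fat-4 and fat-6 had a thresholded summit in the promoter window and fat-1, fat-2, fat-5 and fat-7 did not. In fat-6, a stearoyl-CoA desaturase gene (IV: 11913692 to 11915687, minus strand), the summit at IV: 11915989 lay at -302 bp from the start with a signal value of 254, and an intronic summit had 174. A stronger summit at -1355 bp (309) lay outside the fat-6 window and in the promoter window of another gene. The close relative of fat-6, fat-7 (V: 7151353 to 7153146, minus strand), had its single nearby peak at V: 7150590 to 7150950, beyond the 3' end of the gene and in the promoter window of a neighbour, with a value of 320. The palmitoyl-CoA desaturase gene fat-5 had a summit at -1461 bp from its start (179). The strongest summits near fat-1, the omega-3 desaturase gene, and fat-2, which encodes the oleate desaturase, lay at -1271 and -1223 bp, in intergenic sequence, with values of 580 and 508. Summits past the 3' ends of these genes, with TGATAA, had 522 and 491. The neighbouring front-end desaturase genes fat-4 and fat-3 had promoter summits with values of 195 and 314. An intronic summit of fat-4 at IV: 9801684, or -1339 bp from the start of fat-3, was stronger, at 707.

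As a list, 3 of the 7 desaturases had a promoter peak (42.9%, 95% Wilson interval 15.8 to 75.0) against 18.6% of other protein-coding genes, and the difference did not pass Fisher's exact test (adjusted p = 0.166). With a window from 2000 bp upstream to 500 bp downstream it was 85.7% (adjusted p = 0.00223), and with only the peaks above the median signal 42.9% (adjusted p = 0.0482), both by Fisher's exact test. The second value rests on a narrow margin, since the promoter summit of fat-4 had 194.611 and the median signal was 194.587.

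**Figure D3:**
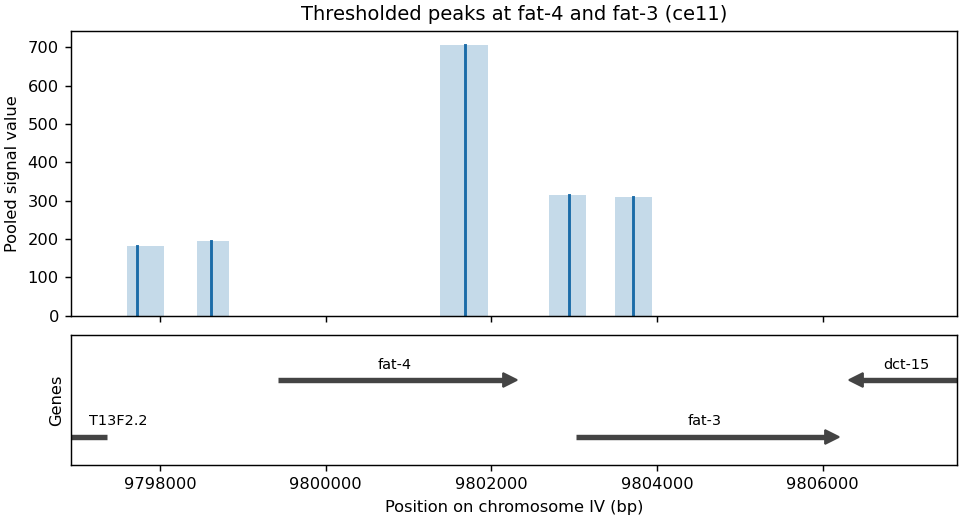
Thresholded peaks (top, shaded from start to end, with a line at the summit and the height giving the pooled signal value in the caller's units) above the protein-coding genes (bottom, arrowheads at the 3' ends) along chromosome IV from 9796929 to 9807619 on build ce11. The strongest of the 5 peaks, at 707, lies in an intron of fat-4 upstream of fat-3.

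Regulators of the same pathway also carried peaks. The nhr-80 locus itself (III: 11985 to 14869, minus strand) had a summit 10 bp downstream of its start with a value of 460 and another at -632 bp with 237. Both lie on sequence that an nhr-80 transgene can also hold, so copies in the genome and in the transgene are not told apart by these lists. For nhr-49, a receptor gene that acts with nhr-80 in fat metabolism (I: 9869651 to 9874680), the summit was at -362 bp with a value of 504. Lower values were found upstream of nhr-13 (-158 bp, 187), of sbp-1, the SREBP homologue (-133 bp, 189), and of acs-2, an acyl-CoA synthetase gene of fatty acid oxidation (-682 bp, 188). The mediator subunit gene mdt-15 had no summit in its promoter window and one at -1854 bp (419). In the lysosomal lipase gene lipl-4 the single summit lay 1694 bp downstream of the start, in the promoter window of another gene (130). At unc-119, the locus mutated in the strain, there was no peak of either the thresholded or the unthresholded list from 2000 bp upstream to 1000 bp past the gene.

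Lipid metabolism lists held more promoter peaks than the rest of the genome, where 3712 of 19973 protein-coding genes (18.6%) had one. Peaks were found at 14 of 20 lipid-regulatory transcription factors and cofactors (70.0%), 11 of 16 lipase and lipid droplet genes (68.8%) and 14 of 22 genes of peroxisomal beta-oxidation and biogenesis (63.6%). They were also found at 8 of 14 genes of fatty acid synthesis and elongation (57.1%), 9 of 16 of sphingolipid metabolism (56.3%), 5 of 9 lipid-binding proteins (55.6%) and 14 of 28 of mitochondrial beta-oxidation (50%). Strong members were the fatty acid elongase gene elo-1 (signal 792), the acyl-CoA synthetase gene acs-1 (731), the ceramide synthase gene hyl-2 (750) and the seipin homologue seip-1 (570). Others were nhr-8 (718), hlh-11 (601), acox-1.1, for a peroxisomal acyl-CoA oxidase (395), cpt-2, for a carnitine palmitoyltransferase (391), and lbp-3, for a fatty acid binding protein (540). By Fisher's exact test, adjusted over 32 lists, these 7 lists had p from 4.58e-06 for the regulators to 0.0229 for the lipid-binding proteins. None of the 7 passed the same exact test against only genes with any peak of the unthresholded list in the window (adjusted p from 0.0509 to 0.647). Mitochondrial beta-oxidation also lost its call above the median signal (21.4%, adjusted p = 0.0939, Fisher's exact test). One-carbon and phosphatidylcholine synthesis did not pass, with peaks at 6 of 17 genes (35.3%, adjusted p = 0.152, Fisher's exact test).

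Intestinal genes had the highest shares. All 6 vitellogenin genes, which encode yolk proteins made in the adult intestine, had a promoter peak, with values of 381 at vit-5, 365 at vit-6, 342 at vit-2 and 310 at vit-1. Of 20 intestine markers, 18 had one (90.0%, 95% Wilson interval 69.9 to 97.2), among them pept-1 (988), the intestinal GATA factor gene elt-2 (710), the vacuolar ATPase gene vha-6 (627) and the cathepsin gene cpr-1 (530). The adjusted p was 0.000119 for vitellogenins and 6.99e-11 for intestine markers by Fisher's exact test. Detoxification genes of the P450, UGT and GST families had peaks at 84 of 185 members (45.4%, adjusted p = 7.64e-16, Fisher's exact test), led by ugt-62 (758). Nuclear hormone receptors had peaks at 81 of 274 members (29.6%, adjusted p = 3.54e-05, Fisher's exact test), led by nhr-35, nhr-68 (773) and nhr-8. Against only genes with any unthresholded peak in the window, the calls of vitellogenins and nuclear hormone receptors ended (adjusted p = 0.0540 and 0.0936, Fisher's exact test), and those of intestine markers and the detoxification families did not. All 6 vitellogenins had a thresholded peak there too (100% against 48.8% of other such genes), so a list of this size could not have scored higher.

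Markers of other tissues carried few promoter peaks. Of 18 hypodermis markers only elt-3 had one (124), of 17 body-wall muscle markers unc-112 (638) and unc-60 (415), of 24 neuron markers egl-21 (168) and snb-1 (95.9), and of 36 germline markers cgh-1 (841) and car-1 (96.0). Of 14 pharynx markers, pha-4 (495) and pqm-1 (234) had one, but pha-4 is also among the lipid regulators and pqm-1 is known for its expression in the intestine. None of these 5 lists passed Fisher's exact test against the other genes, with adjusted p from 0.0773 for germline to 1 for pharynx. The lists have only 14 to 36 genes, so a lower share could have been missed.

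Several lists of the basic cell machinery, though not mitochondrial ribosomal proteins or histones, also held more peaks than other genes. Cytosolic ribosomal protein genes had them at 55 of 81 members (67.9%, 95% Wilson interval 57.1 to 77.1, adjusted p = 4.73e-21, Fisher's exact test), with rpl-3 (1388), rpl-20 (830), rpl-15 (815) and rpl-1 (785) the strongest. When each summit counted only for its nearest start, the share was 37.0% (adjusted p = 7.81e-06, Fisher's exact test). The vacuolar ATPase list had 13 of 20 (65.0%), led by vha-13 (925), and oxidative phosphorylation had 19 of 41 (46.3%), led by cox-5B (891). Autophagy had 10 of 22 (45.5%), led by lgg-2 (519), the proteasome 14 of 33 (42.4%), led by rpn-9 (253), and heat shock proteins and chaperonin 12 of 30 (40%), led by hsp-3. The adjusted p of these 5 lists ran from 2.58e-05 to 0.0122 by Fisher's exact test. With only the peaks above the median signal, the proteasome (3.03%), heat shock proteins, autophagy and mitochondrial beta-oxidation did not pass the same exact test. The calls of heat shock proteins (20%) and the proteasome (27.3%) also ended by nearest start, and that of heat shock proteins with the wide window (40%) and without replicate 2 (33.3%).

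Lower shares than in other genes were found for chemoreceptors, with 28 of 1293 (2.17%), cuticle collagens, with 9 of 156 (5.77%), and major sperm proteins, with 0 of 31, which allows a share of up to 9.68%. Fisher's exact test gave adjusted p of 3.38e-78, 2.58e-05 and 0.00696. Mitochondrial ribosomal proteins (14 of 70), histones (9 of 72), homeobox ceh genes (6 of 63), insulin-like peptides (4 of 39) and C-type lectins and lysozymes (53 of 256) did not differ from other genes, with adjusted p from 0.106 to 0.783 in the same exact test. Each list was also tested against only those genes that had any peak of the unthresholded pooled list in the window. There, 3 lists were higher: intestine markers (90.0%), cytosolic ribosomal proteins (76.4%) and the P450, UGT and GST families (66.1%), with adjusted p of 0.00131, 7.12e-05 and 0.00110 by Fisher's exact test. The other 14 lists that were higher against all genes did not pass, including the 7 of lipid metabolism and the vitellogenins. Their shares ran from 51.9% for the proteasome and 54.3% for oxidative phosphorylation, close to the 48.8% of other such genes, to 88.9% for fatty acid synthesis and 100% for vitellogenins. On the lower side, chemoreceptors (36.8%) and major sperm proteins lost their calls (adjusted p = 0.0936 and 0.422, Fisher's exact test). Collagens (23.7%), germline markers (8.70%) and mitochondrial ribosomal proteins (28.6%) were lower there, with adjusted p of 0.0115, 0.00110 and 0.0314 in the same exact test.

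**Figure D4:**
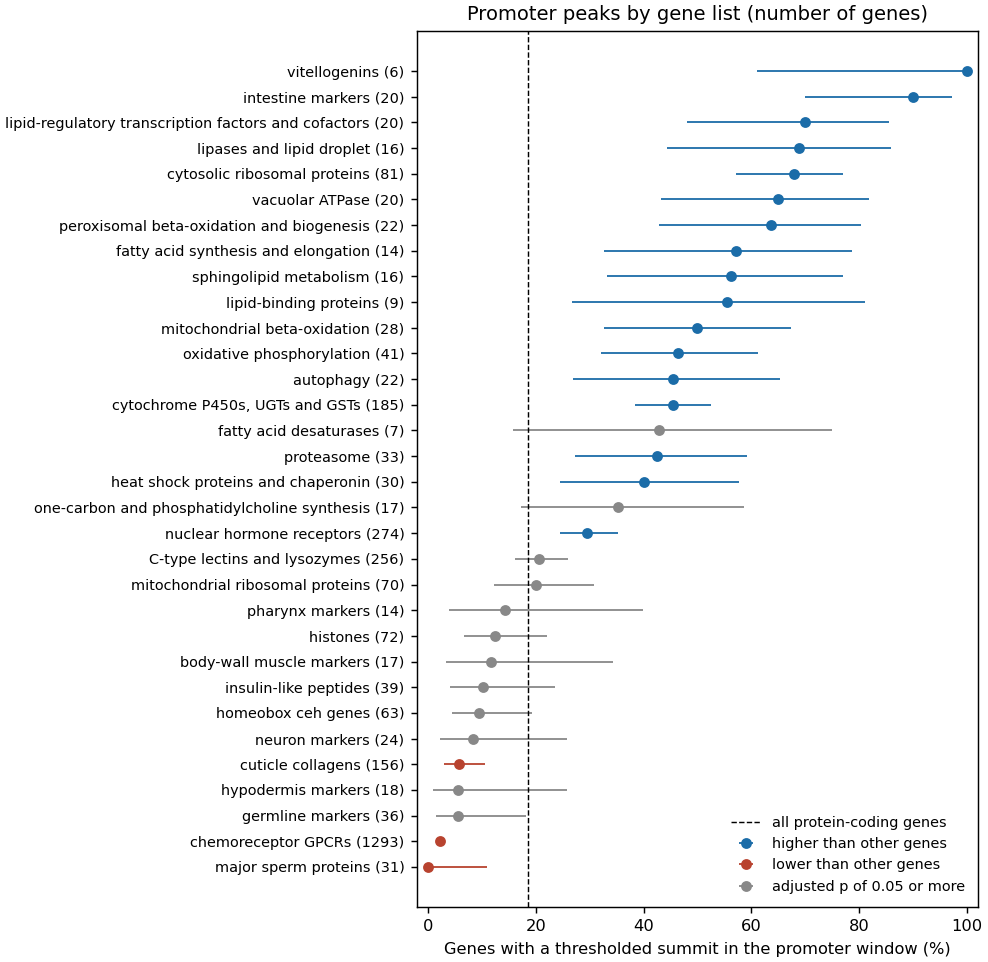
Share of each list's genes with a thresholded summit in the promoter window (x axis, percent, with 95% Wilson intervals) for the 32 lists (y axis, number of genes in parentheses), coloured by the outcome of Fisher's exact test. Vitellogenins (100%) and intestine markers (90.0%) lie farthest above the 18.6% of all protein-coding genes, and major sperm proteins (0%) lie lowest.

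The last question was which sequences lay under the summits. The GATA sequence TGATAA, which intestinal ELT factors are known to bind, lay within 50 bp of 2634 of the 7020 summits (37.5%) and in flanks of the same width at 790 (11.3%). In the replicates' own lists it was at 36.4% ± 0.369 (SD, n = 2) of summits. By p-value in the McNemar test it ranked first of all 2080 distinct 6-mers, followed by its overlapping neighbours CTTATC (26.3% against 5.03%) and CTGATA (20.3% against 4.97%). By the ratio of summits to flanks it was not first, since TGATAA had 3.33, CTTATC 5.23 and ACGCAG 4.79. The nuclear receptor half-site AGGTCA lay at 3.28% of summits and 2.45% of flanks, a ratio of 1.34. A control sequence with the same letters, GATGCA, lay at 4.12% and 3.11%, a ratio of 1.33. The E-box CACGTG lay at 4.19% and 1.91%. Of the HNF4-type sequences, CAAAGTCCA lay at 11 summits and 2 flanks, CAAAGTC at 67 and 71, and the direct repeat AGGTCAAAGGTCA at 0 of 7020.

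The exact McNemar test, two-sided and adjusted over the 7 sequences, gave 3.77e-285 for TGATAA and 1.20e-14 for CACGTG. It gave 0.00610 for AGGTCA, 0.00371 for the control GATGCA, 0.0314 for CAAAGTCCA and 0.930 for CAAAGTC. In each replicate's own list AGGTCA did not pass the same exact test, with adjusted p of 0.0705 in replicate 1 and 0.161 in replicate 2, and CAAAGTCCA did not pass either (0.592 and 0.251). Other leading 6-mers were GAGAGA (19.3% against 6.47%) and CGTCTC (12.1% against 3.28%), while AT-rich 6-mers such as AAAATT were fewer at summits (0.52 times as many as in flanks). By the McNemar test adjusted over all 2080 distinct 6-mers, 918 were called higher at summits and 467 lower. A pass alone, as for AGGTCA, GATGCA or CACGTG, therefore does not set a sequence apart. The G and C content was 41.5% near summits and 35.1% in the flanks.

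**Figure D5:**
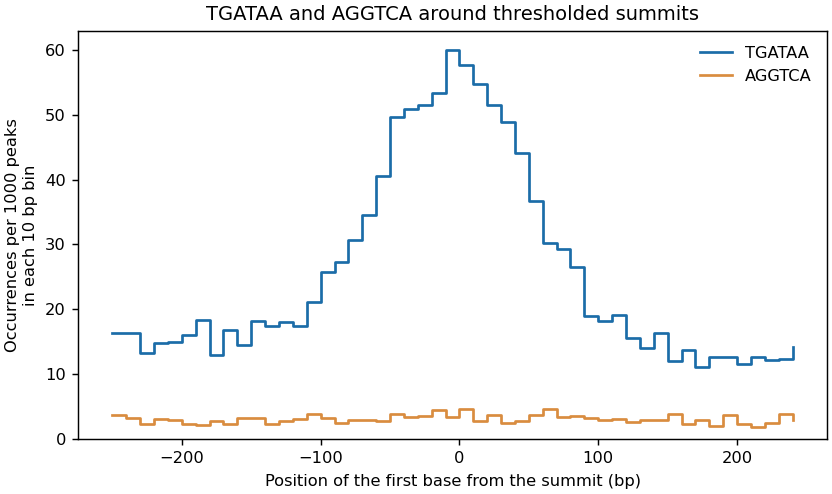
Occurrences of TGATAA and AGGTCA on either strand per 1000 thresholded peaks (y axis) in bins of 10 bp from 250 bp upstream to 250 bp downstream of the summit along the chromosome (x axis). TGATAA rises to 60 per 1000 peaks at the summit, and AGGTCA stays between 1.85 and 4.56.

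The authors processed the same libraries on builds ce10 and ce11, which shows how far the thresholded list depends on that processing. On ce10 the list held 9962 peaks and on ce11 7038, a ratio of 1.42, although both pooled lists held 30000 peaks. In each build the thresholded list was exactly the strongest part of the pooled list, down to a signal value of 52.3 on ce10 and 93.0 on ce11. The median width of thresholded peaks was 480 bp on ce10 and 416 bp on ce11. Chromosome X held 22.6% of the nuclear peaks on ce10 and 23.2% on ce11. A ce11 list lengthened to 9962 peaks also had 22.6% on X, so the length of the list was enough to give that share.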

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

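The tests of the weaker unthresholded peaks, of the intestine markers and of peak widths were chosen only after their results were seen. The predictions for base composition, shared vitellogenin reads, transcribed genes and replicate overlap were written before, but the judgement of some was changed afterwards. The vitellogenin pattern was stated at first for 4 of the 6 genes and was narrowed to vit-6 once the other summits were seen to lie near the gene starts. The comparison with long genes was added after the count for the vitellogenins was known, and it turned that test from a fit into an open one. The peak width of replicate 1 was judged a fit at first and then left open. Another pattern, of peaks at ribosomal and respiratory genes without TGATAA, was tested against the muscle markers and then dropped from the weighing, and its values are given only as description.

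A signal outside the comparisons came from mitochondrial DNA, where the thresholded list had 18 peaks. The strongest peak of the whole list was there, from 4143 to 6647, with the highest signal value, and the peaks covered 9732 of the 13794 bp. Replicate 1 had 18 such peaks among its strongest 7038 and replicate 2 had 19. They are given here because they lie outside the nuclear comparisons and exceed the 3 that a count of 0 allows. That limit is no expected count for DNA of high copy number, so no excess was tested.

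The 6-mer that ranked first by p-value in the McNemar test was a GATA site (37.5% of summits and 11.3% of flanks). The ratio of summits to flanks was 1.34 for the receptor half-site AGGTCA and 1.33 for its control. Within 25 bp of the summit these ratios were 1.82 and 1.55, and within 100 bp 1.19 and 1.18. Above the median signal they were 1.15 and 1.47. The difference between the half-site and its control was not tested. Base composition was excluded as the cause of the TGATAA excess. Among 54 other 6-mers of the same letters without GATA or TATC, the highest ratio of summits to flanks was 1.39, for AATGAT, against 3.33 for TGATAA. A habit of the peak caller at any peak it lists also failed its test, which was chosen after its result was seen. The ratio was 0.929 among the 14990 weakest unthresholded peaks, with TGATAA at 9.45% of summits and 10.2% of flanks. The unthresholded list also holds background, so this test cannot decide on an effect limited to strong peaks. Sites held by other intestinal factors, such as ELT-2, remain open: promoter peaks at 90.0% of intestine markers go with such sites and with binding of NHR-80 itself, and no other factor or untagged strain was analysed here, so these cannot be told apart.

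The widest thresholded interval covered a gene body. It spanned 6268 bp (IV: 8260657 to 8266924) around vit-6 (IV: 8261157 to 8266459), with 6 summits, 2 of them in coding exons more than 200 bp past the start. Reads shared with other vitellogenin copies by an exact match of 50 bp were excluded for vit-6. Of its coding 50-mers 0% recur in the genome (for vit-3 and vit-4 it is 79.7% and 83.8%). Shorter matches and matches with mismatches were not counted, so reads placed that way are not covered. Enrichment along heavily transcribed genes stays open. Of the other 5 vitellogenin genes, 4 had unthresholded summits in coding exons past the promoter window. The exception was vit-4, where 83.8% of coding 50-mers recur, though vit-3, at 79.7%, had 2 such summits. However, 44.2% of 321 genes with coding sequence as long had such summits too, and the exact binomial test of the excess gave 0.124.

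The thresholded list was 1.42 times as long on ce10 as on ce11. The replicates did not overlap more on ce10: their 9962 strongest peaks overlapped at 92.2% on ce10 and 92.3% on ce11, a difference of -0.171 percentage points. The overlap does not measure how well ranks reproduce, from which IDR sets its limit. Rank agreement on ce10 was not examined, so closer ranks there stay open. The most common peak width of replicate 1 was 480 bp on ce11 and 476 bp on ce10, a change of 4 bp, while it was 476 bp in replicate 2 and 480 bp in the pooled list on both builds. Whether replicate 1 was called with another fragment length, and whether that moved the threshold, cannot be told, because the caller's settings are unknown, the overlap hardly moved and the IDR step was not rerun here. No biological explanation was tested for any of these patterns, since the design has 1 group.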

How the results depend on the processing

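The longer list and the list without peaks near small RNA genes were chosen after seeing the data. Under the alternatives run for them, the promoter share (37.2% to 61.3%, by window) and the X share (22.6% to 24.5%) kept their direction and call, as did TGATAA and CACGTG. The replicate overlap of 89.9% moved to 99.9% for peaks above the median signal, 67.4% with overlap of 50% of each peak, 85.2% for summits within 100 bp, 87.7% for the top 1000 peaks and 90.5% for the longer list. Against the replicates' full lists, 99.7% of all thresholded peaks overlapped both, so the share depends on how long those lists are. The 99.9% therefore does not by itself show closer agreement of strong peaks. A single replicate gave 94.4% to 94.8%, since 1 list is easier to overlap than both. The rank correlation of the replicates' signal values was 0.91 above the median signal. The median distance to a start was 880 bp in the longer list and 834 to 862 bp with 1 replicate left out. The 17 lists above other genes became 3 against genes with any listed peak, and from 14 to 19 otherwise, and the 3 below became 5 with the window of 500 to 100 bp, 4 with the wide window and without replicate 2, and 2 above the median signal. The 5 sequences above flanks became 3 above the median signal, 3 without either replicate and 4 within 25 bp, where CAAAGTCCA lost its call. AGGTCA lost its call above the median signal and without either replicate, and kept it within 25 or 100 bp and in the longer list. Its control GATGCA kept its own in all.

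Of 288 values of single lists, 241 kept direction and call, and 4 of the 20 called lists kept theirs throughout. Against genes with any listed peak, calls were lost for fatty acid synthesis and elongation (88.9%), lipid regulators (73.7%), mitochondrial (66.7%) and peroxisomal (73.7%) beta-oxidation, lipases (84.6%), lipid-binding proteins (71.4%), sphingolipids (60%) and vitellogenins (100%). They were also lost there for autophagy (58.8%), proteasome (51.9%), vacuolar ATPase (72.2%), oxidative phosphorylation (54.3%), heat shock proteins (57.1%), nuclear hormone receptors (57.9%), chemoreceptors (36.8%) and major sperm proteins (0%), while germline markers (8.70%) and mitochondrial ribosomal proteins (28.6%) became lower and passed. Above the median signal, calls were lost for mitochondrial beta-oxidation (21.4%), autophagy (22.7%), heat shock proteins (13.3%) and major sperm proteins (0%), and gained for desaturases (42.9%). By nearest start they were lost for the proteasome (27.3%) and heat shock proteins (20%), which also lost theirs with the wide window (40%) and without replicate 2 (33.3%, against 40% without replicate 1). Calls were gained with the wide window for desaturases (85.7%), one-carbon genes (58.8%) and germline markers (5.56%), and with the narrow one for ceh genes (4.76%) and insulin-like peptides (0%). The longer list gained one-carbon genes (52.9%) and mitochondrial ribosomal proteins (37.1%). Leaving out replicate 2 gained one-carbon genes (41.2%, against 35.3% without replicate 1) and germline markers (2.78%, against 5.56%).

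Directions turned for mitochondrial ribosomal proteins (8.57% above the median signal, 12.9% with the narrow window, 10% by nearest start, 28.6% against genes with any listed peak) and the proteasome (3.03% above the median signal). They also turned for muscle markers (11.8% above the median signal), pharynx markers (14.3% there, 28.6% with the wide window), and muscle, pharynx and neuron markers (each 50% against genes with any listed peak). By nearest start the pharynx share (14.3%) stayed below that of other genes (15.4%), and only its odds ratio with 0.5 added to each count turned. CAAAGTC turned from fewer to more at summits above the median signal (0.0856 percentage points) and without replicate 1 (0.0285, against -0.199 without replicate 2). The cause of these changes was not tested. Depth limits are unknown, as no read counts were used. No paired analysis was possible because the study has 1 group.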

Other observations

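All tests in this part were chosen after the data were seen, and they are described here without an explanation.

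Peaks lay at many genes of small RNAs. Of 612 nuclear tRNA genes, 263 (43.0%) had a thresholded summit within 200 bp, and 239 summits lay there against a mean of 20.9 and at most 34 in 100 shifts. The small nucleolar RNA genes, which guide ribosomal RNA modification, had 97 summits against a mean of 11.8, and the spliceosomal small nuclear RNA genes had 23 against 4.14. Near microRNA genes there were 25 against 8.47 and near lincRNA genes 56 against 22. Replicate 1 had 246 of its strongest summits near tRNA genes and replicate 2 had 231. TGATAA was less frequent at the first 3 of these classes, with 13.4% of tRNA summits and 2.06% of small nucleolar RNA summits against 38.4% and 38.0% of the other summits, and 0% of small nuclear RNA summits against 37.6% (adjusted p = 1.55e-16, 1.13e-16 and 5.28e-05, Fisher's exact test over 5 classes). At microRNA genes it lay at 20% and at lincRNA genes at 41.1%, and neither passed the same exact test (adjusted p = 0.120 and 0.582).

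Promoter peaks of different gene groups also differed in TGATAA. It lay at the strongest promoter peak of 16 of 18 intestine markers (88.9%), 9 of 11 lipase and lipid droplet genes (81.8%), 10 of 14 peroxisomal genes (71.4%) and 35 of 51 peaks of C-type lectins and lysozymes (68.6%). It lay at 3 of 53 peaks of cytosolic ribosomal protein genes (5.66%) and 0 of 19 of oxidative phosphorylation, against 37.0% and 36.7% of other promoter peaks. By Fisher's exact test over 24 lists with at least 5 peaks, these 6 lists passed, with adjusted p from 7.28e-06 for ribosomal proteins to 0.0402 for peroxisomal genes. At the 25 named genes with the strongest promoter peaks TGATAA lay near 2 summits, those of F16G10.6 and pcp-1. Among all promoter peaks it was at 26.0% of the 100 strongest, 38.8% of the next 400, 43.8% of those ranked 501 to 1000, 38.7% of the next 1000 and 29.9% of the rest.

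A pair of longer sequences was built by extending leading 6-mers from these same summits, so their excess was fixed by that choice. McNemar values computed for them therefore carry no weight and are not given. ACTGATAAG lay at 350 summits and 24 flanks (4.99% and 0.342%), and CTGCGTCTC at 333 and 37 (4.74% and 0.527%). Down the unthresholded list, TGATAA lay at 43.4% of the 2000 strongest nuclear summits, 18.5% of those ranked 10001 to 12000 and 13.1% of the next 2000, where flanks had 13.7%. Chromosome X held 25.8% of the strongest 2000 and 19.2% of those ranked 12001 to 14000, a difference that was not tested.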
